A study of Mus musculus with 18 samples.

How the data were processed

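RNA sequencing measured mRNA in cultured MC38 cells and MC38 tumours, and guide sequencing measured the abundance of CRISPR guides in MC38 cells recovered from implanted mice. Samples were grouped by their titles and genotype labels into control and Mbtps1-knockdown cells (3 libraries each), control and Mbtps1-knockdown tumours (5 each), and 1 screen library each from C57BL/6 and Rag1-knockout mice. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was captured on beads, and libraries were built with a VAHTS kit for Illumina. The deposited gene table holds whole-number read counts per gene symbol, and the deposited guide table holds whole-number read counts per guide, neither of them normalised by the authors. The submitters' processing notes name FastQC 0.11.9, cutadapt 1.18, STAR 2.7.1a, SAMtools 1.3.1, Cufflinks 0.17.3 and HTSeq 0.13.5, without saying which was used for what, and they name the human build hg38. The genes of the table carry mouse symbols, of which 14957 of 15596 (95.9%) are in the GENCODE M21 annotation of GRCm38, so the alignment reference is taken to be a mouse genome whose build is not given in the sources used here. Whether counting used strand is likewise not given, so reads of a gene and an overlapping or antisense partner cannot be separated, and near-identical genes share reads.

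The table holds 15596 symbols in 16 libraries. Of these, 15274 have counts in the tumour part and 13014 in the cell part, 12692 in both. The lowest non-zero sum over a part is 13 in cells and 15 in tumours, so genes with fewer counts appear to have been set to 0 before deposit, and a gene at 0 in one part is called listed at 0. A group of 154 symbols has the same counts as another symbol in every library. No value column lacked a sample. Total counts ranged from 14240353 to 15515405 in cells and from 19630410 to 32655739 in tumours. Tumours were therefore sequenced more deeply, and they had more replicates.

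Differential expression was computed with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, robust dispersions, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter removed 1109 genes in cells and 1277 in tumours. Each comparison used only its own libraries. The standard error is the log2 fold change divided by the root of the F statistic. Levels are CPM, counts scaled to the library total, with the SD over libraries. The square root of the common dispersion was 0.116 in cells and 0.159 in tumours. The interaction used all 16 libraries in 1 fit over the genes with counts in both parts. Mitochondrial mRNAs carry the symbols ND1 to CYTB in the table.

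A set of 31 gene lists was fixed before the data were examined, covering lipid synthesis, endoplasmic reticulum stress, secretion, lysosome, interferon, antigen presentation, inflammation, proliferation, hypoxia, matrix, immediate early and mitochondrial genes and markers of cell types a tumour could hold. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, voom values), 17 lists in cells and 29 in tumours. Camera compares a list with all other genes. With the correlation estimated by camera from the data, 0 lists passed in either comparison, so the calls depend on the preset value; 2 lists in cells and 4 in tumours then had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move on balance one way, was passed by 3 of the 17 lists in cells and by 13 of the 29 in tumours. Other splits of the libraries passed a median of 7 lists in cells and 10 in tumours with the preset correlation. The screen had 4 lists of its own.

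Named genes followed a rule set before the data were examined: Mbtps1; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes and receptor segments; up to 4 members with the smallest p in the direction of each list past its test and 1 or 2 of other lists; 12 immune and lipid genes always; and, for the interaction, the 5 largest differences each way under the same limits, with no overlap in cells or in tumours. Xist, H19, Ptprc, the hexamer and genes named only in the closing section were chosen after their values were seen. Some genes that the rule takes are not reported here.

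For the screen, the log2 ratio of CPM with a pseudocount of 1 was taken for guides with at least 20 reads over both libraries, and genes were summarised by the median over guides. With 1 library per genotype no test was made. The median was placed among 10000 random sets of as many guides matched on mean abundance, a description of these 2 libraries. Reads carry no molecular identifiers, so counting intervals and floors of 3 counts cover counting error only.

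Alternatives were size factors from DESeq2, library totals, no filter and a stricter filter (at least 1 CPM and 10 counts), the replicate number as a block, a fit over all 16 libraries, DESeq2 1.42.0, limma voom with and without sample quality weights, glmTreat against a fold of 1.5, and each library left out in turn, with other pseudocounts, minimum reads, scalings and summaries for the screen. After seeing the data, a loess correction for transcript GC content and length, the tumours without the 2 libraries of highest mitochondrial share, the cells without genes holding the hexamer CTCGGA, and an exact permutation test of list means in tumours were added. Transcript and 3' untranslated sequences came from GENCODE M21, with the longest annotated region per gene, and the hexamer scan took genes with at least 50 bases of it, adjusting for its length and GC content. The hexamer scan covered 91.2% of the genes tested in cells, and the GC correction 96.4% of those in cells and 96.3% in tumours.

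The edgeR comparisons of cells and of tumours, camera, the hexamer scan and the placement of screen genes were tested on simulated data. The interaction, fry, the exact permutation test, the GC and length correction, DESeq2 and the limma voom fits were not. With the vesicle traffic list raised by a fold of 1.5, camera found it in both comparisons. It also passed 0 other lists in cells and 1 in tumours. Genes were drawn independently there, so the preset correlation was not checked. For counts drawn from the real means and library sizes with 200 genes changed, the cell comparison recovered 53.2% of the genes changed by a fold of 1.5, 84.1% at 2 and 97.1% at 4, with 4.35% of calls false over 11802 genes. The tumour comparison recovered 58.5%, 83.1% and 98.4%, with 5.42% of calls false over 13886 genes. A planted hexamer effect of -0.3 over 10856 genes was found as -0.30 and ranked 1. In the screen, 195 of 200 genes shifted by a log2 of 2 lay outside the central 95% of random sets (97.5%), as did 5 of 200 unshifted genes, over 18108 guides. All these genes had 4 kept guides, and the guides of a shifted gene moved alike. The share therefore does not apply to Mbtps1, which had 2 kept guides.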

Results

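The series holds 16 RNA sequencing libraries and 2 libraries of a pooled CRISPR screen, all made from MC38, a mouse colon adenocarcinoma line that forms tumours in C57BL/6 mice. The RNA libraries were 3 of control cells, 3 of Mbtps1-knockdown cells, 5 of control tumours and 5 of Mbtps1-knockdown tumours. The sample labels call the depletion a knockdown, and the series description calls it a knockout. Mbtps1 encodes site-1 protease, a membrane-bound protease of the secretory pathway. It cuts the SREBP factors of lipid synthesis and the stress sensor ATF6, a step in the release of their active parts. The gene lies on chromosome 8, from 119508156 to 119558735 on the minus strand of GRCm38. Total counts per library ran from 14240353 to 15155599 in control cells (n = 3), from 14931689 to 15515405 in knockdown cells (n = 3), from 19630410 to 28316572 in control tumours (n = 5) and from 22257519 to 32655739 in knockdown tumours (n = 5). No pair of replicates agreed within counting noise, the lowest chi-square per degree of freedom being 6.10. The labels do not state that replicates were separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

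The first comparison asked which genes differ between Mbtps1-depleted and control MC38 cells in culture. Mbtps1 stood at 129, 135 and 118 CPM (counts scaled to the library total) in the 3 control libraries and at 37.0, 35.7 and 34.8 in the 3 knockdown libraries, a log2 fold change of -1.84 (SE 0.09, adjusted p = 3.1e-06). By camera with the preset correlation, genes of cholesterol synthesis, fatty acid synthesis and vesicle traffic were lower in the knockdown cells. Genes of the interferon response, inflammatory signalling and the integrated stress response were higher by the same test. With an estimated correlation 0 of the 17 lists passed. Of 11905 genes tested, 448 were higher and 663 lower in knockdown cells, 1111 in all (9.33%), of which 105 rose and 67 fell by more than 2-fold. The 2 groups did not overlap in 3780 genes (31.8%), where chance gives 10%.

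**Figure D1:**
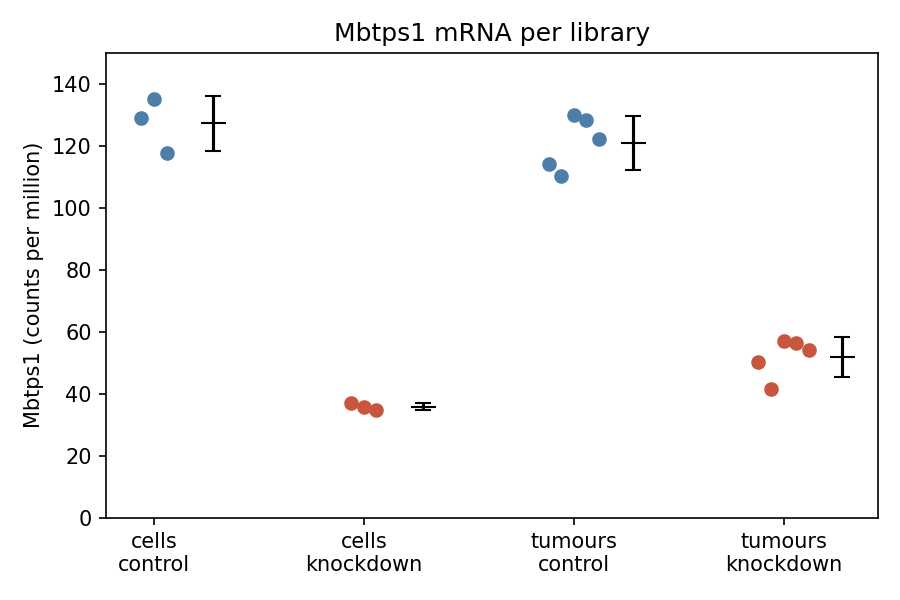
Mbtps1 in CPM (vertical axis) for each of the 16 RNA libraries (points), with the mean and SD of each group beside them (bars). The knockdown cells averaged 35.8 against 127 in control cells, and the knockdown tumours 51.8 against 121 in control tumours.

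Cholesterol synthesis and uptake genes, targets of the SREBP factors, formed the list with the smallest adjusted p by camera with the preset correlation. Vesicle traffic genes had a smaller one with an estimated correlation. With fry, vesicle traffic and NF-kappa-B genes had smaller ones (adjusted p = 0.0113 each, against 0.0279 for cholesterol genes). Of 25 measured members, 17 fell, 0 rose and 8 did not pass, and 17 fell when adjusted over the list alone. The median log2 fold change was -0.57 (camera adjusted p = 4.4e-13, and adjusted p = 0.310 with an estimated correlation). Among them were Cyp51, a demethylase of the sterol ring (-0.77, SE 0.09, adjusted p = 6.1e-04), Idi1, an isomerase of the isoprenoid steps (-0.79, SE 0.10, adjusted p = 9.7e-04), and Insig1, which retains SREBP in the endoplasmic reticulum (-0.93, SE 0.13, adjusted p = 0.0015). Fatty acid synthesis genes were lower too, with 7 of 17 members down, 0 up and 10 not passed (11 down when adjusted over the list alone), a median of -0.35 and a camera adjusted p of 5.6e-07 (adjusted p = 0.310 with an estimated correlation). The elongase Elovl6 (-0.74, SE 0.12) and the desaturase Scd1 (-0.64, SE 0.11) were examples. Of 21 genes of vesicle traffic between endoplasmic reticulum and Golgi, 9 fell, 0 rose and 12 did not pass (10 fell when adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.5e-06, and adjusted p = 0.274 with an estimated correlation). The coat protein genes Sec23a (-0.74, SE 0.11) and Sec31a (-0.50, SE 0.09) and the retrieval receptor gene Kdelr3 (-0.89, SE 0.14) were among them. Endoplasmic reticulum chaperones and degradation factors, the targets of ATF6 and XBP1, did not shift. With edgeR 0 of 24 members passed in either direction, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05; DESeq2 and limma voom called 0 as well. The chaperone median was 0.00 (camera adjusted p = 0.840). Hspa5, the chaperone BiP, had a log2 fold change of 0.14 (SE 0.09, adjusted p = 0.34).

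Interferon gamma response genes were higher in knockdown cells. Of 19 measured members, 8 rose, 0 fell and 11 did not pass (13 rose when adjusted over the list alone). Their median log2 fold change was 0.46 (camera adjusted p = 1.1e-07, and adjusted p = 0.310 with an estimated correlation). Cxcl10, a chemokine for activated T cells, went from 37.5 ± 1.89 to 75.1 ± 7.60 CPM (0.99, SE 0.11, adjusted p = 3.8e-04), and the guanylate-binding protein gene Gbp4 (1.44, SE 0.19) and the cytokine signalling inhibitor gene Socs1 (1.17, SE 0.18) rose as well. Cd274, which encodes the PD-L1 ligand, rose by 0.69 (SE 0.15, adjusted p = 0.016), while Irf1 (0.33, SE 0.11, adjusted p = 0.095) and B2m (-0.10, SE 0.09, adjusted p = 0.54) did not pass. Of 15 NF-kappa-B target and cytokine genes, 7 rose, 0 fell and 8 did not pass, likewise 7 when adjusted over the list alone, with a median of 0.43 (camera adjusted p = 2.1e-05, and adjusted p = 0.310 with an estimated correlation). Ccl7, a monocyte chemokine (1.29, SE 0.14), and Csf1, the macrophage growth factor (0.55, SE 0.09), were examples. Type I interferon response genes gave 3 risers, 0 fallers and 27 not passed of 30 (4 risers when adjusted over the list alone), a median of 0.46 and a camera adjusted p of 2.0e-04 (adjusted p = 0.726 with an estimated correlation). Without control replicate 3 the median was 0.18 and the adjusted p 0.206, and without knockdown replicate 1 the median was 0.25 (adjusted p = 0.0024). The risers were Zbp1, a sensor of left-handed nucleic acid (2.31, SE 0.51), Bst2 (0.54, SE 0.13) and Ifit3 (1.06, SE 0.29). Among 20 genes of MHC class I presentation, 6 rose, 0 fell and 14 did not pass (6 rose and 1 fell when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0079, and adjusted p = 0.726 with an estimated correlation). The immunoproteasome gene Psmb10 (1.04, SE 0.17) and the proteasome activator gene Psme2 (0.65, SE 0.13) were examples. The presentation list did not pass without control replicate 3 (median 0.14, adjusted p = 0.212), without knockdown replicate 3 (0.0734) or with a correction for transcript GC content and length (0.161).

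Integrated stress response genes, the targets of ATF4 and CHOP, included 6 that rose, 1 that fell and 17 that did not pass of 24, the same counts when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 9.3e-04, and adjusted p = 0.726 with an estimated correlation; 0.0804 without control replicate 3, where the median was 0.12). With the correction for transcript GC content and length the median was 0.11 (adjusted p = 0.0014). Ddit3, which encodes CHOP (0.72, SE 0.11), and the amino acid transporter subunit gene Slc3a2 (0.55, SE 0.10) rose. Hypoxia and glycolysis genes had 4 of 23 members down, 0 up and 19 not passed (5 down when adjusted over the list alone), a median of -0.37 and a camera adjusted p of 0.0026 (adjusted p = 0.726 with an estimated correlation). That list did not pass without control replicate 2 (median -0.19, adjusted p = 0.0953) or without knockdown replicate 2 (0.0927), and without control replicate 3 its median was -0.56. The 3' untranslated regions of 5 of its 23 members hold the hexamer CTCGGA, and without genes holding it the hypoxia median was -0.19 (adjusted p = 0.028) and the NF-kappa-B median 0.26 (adjusted p = 1.5e-04). Pdk1 (-0.71, SE 0.12) and the glycolytic enzyme genes Pgam1 (-0.65, SE 0.13) and Hk2 (-0.66, SE 0.13) fell. With the preset correlation, 9 lists passed for the real grouping and a median of 7 for other splits of the 6 cell libraries. Another 7 lists did not pass camera: proliferation (median 0.05, adjusted p = 0.149, but 0.0203 without control replicate 3), immediate early genes (-0.03, 0.249), extracellular matrix and TGF-beta genes (-0.10, 0.355), macrophage markers (0.50, 0.432), mitochondrially encoded mRNAs (0.04, 0.641), lysosomal genes (0.01, 0.679) and fibroblast markers (-0.12, 0.774). The camera direction was upward for the immediate early and fibroblast lists, against the sign of their medians. Mitochondrial mRNAs took 4.20% ± 0.50004 of counts in control and 4.31% ± 0.597 in knockdown cells (n = 3 each).

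By the size of the change, the highest rises among well-expressed genes without overlap between the groups were Prl2c2 (2.12, SE 0.26), Prrx2, a homeobox transcription factor gene (1.76, SE 0.21), Prl2c3 and Prl2c4 (1.61 each, SE 0.26), Tgtp2, an interferon-induced GTPase gene (1.57, SE 0.26), and Hspa1b, an inducible heat shock protein gene (1.56, SE 0.13). Prl2c2, Prl2c3 and Prl2c4 are near-identical proliferin genes, and Prl2c3 and Prl2c4 held identical counts in every library, so their shares of the reads are uncertain. Besides Mbtps1 itself, the deepest falls under the same limits were in Acpp, an acid phosphatase gene (-2.36, SE 0.27), Wasf1, a regulator of actin assembly (-1.73, SE 0.14), Galnt7, a glycosyltransferase gene (-1.64, SE 0.10), Tmem185a (-1.52, SE 0.12) and the kinase gene Lmtk2 (-1.51, SE 0.11). The annotated 3' untranslated regions of Acpp, Wasf1, Galnt7, Tmem185a, Pgam1 and Hk2 hold the hexamer CTCGGA. Across 10856 genes with an annotated 3' untranslated region, 205 of the 1119 with this hexamer fell (18.3%), against 433 of the 9737 without it (4.45%). Without control replicate 1, 2 or knockdown replicate 1 the number of changed genes was 290, 466 or 330, and 27, 15 or 24 of the 68 genes taken by the naming rule lost their call.

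**Figure D2:**
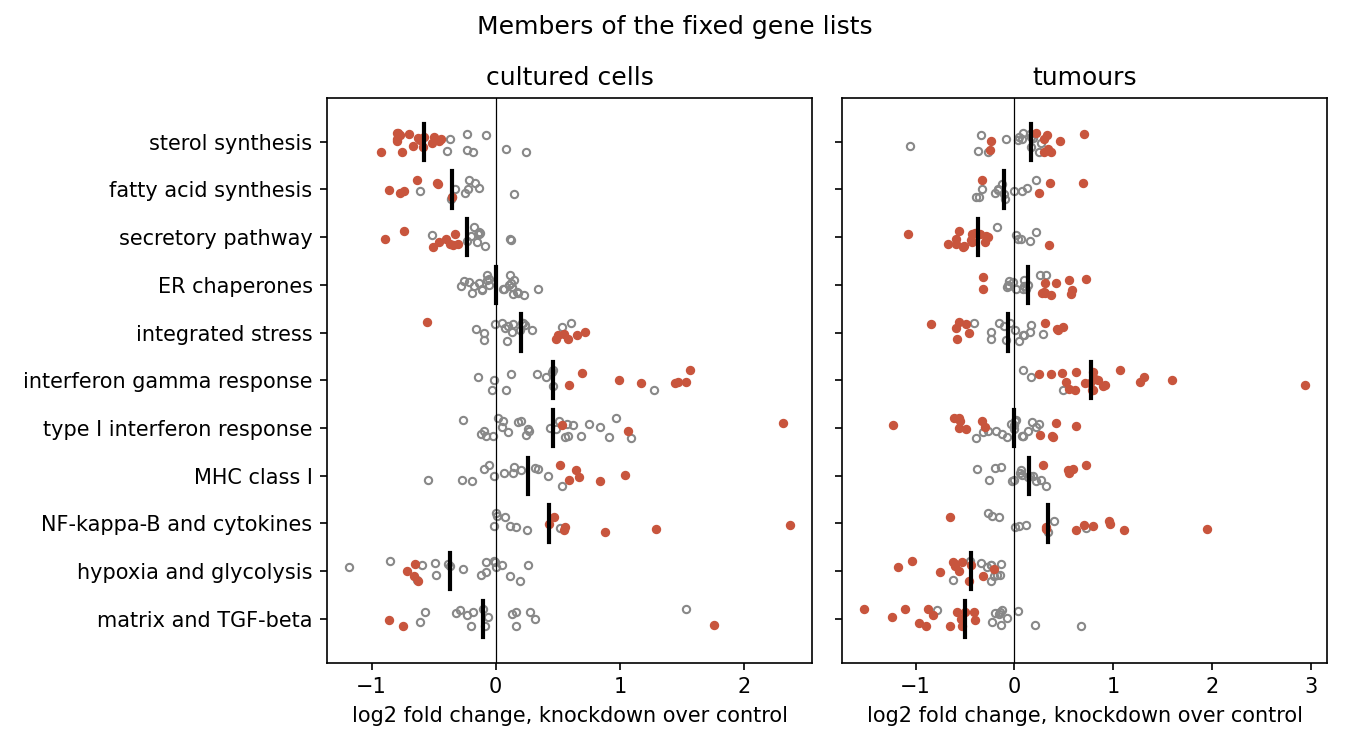
Log2 fold change of knockdown over control (horizontal axis) for each measured member of 11 gene lists in cultured cells and in tumours. Filled points passed at an adjusted p under 0.05, open points did not, and the black bar is the list median, which for sterol synthesis was -0.57 in cells and 0.16 in tumours.

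The second comparison asked which genes differ between Mbtps1-knockdown and control MC38 tumours, whose libraries hold RNA of host cells as well as of cancer cells. Mbtps1 stood at 114, 110, 130, 129 and 122 CPM in the 5 control tumour libraries and at 50.1, 41.4, 57.1, 56.3 and 54.1 in the 5 knockdown tumour libraries, a log2 fold change of -1.21 (SE 0.09, adjusted p = 1.2e-05). Genes of T cells, natural killer cells, their cytotoxic granules and the response to interferon gamma were higher in the knockdown tumours. Genes of the extracellular matrix, vesicle traffic, hypoxia and the endothelium were lower. These rises and falls are camera calls with the preset correlation, and with an estimated one 0 of the 29 lists passed. Of 13997 genes tested, 2816 were higher and 2561 lower, 5377 in all (38.4%), of which 377 rose and 246 fell by more than 2-fold. The groups did not overlap in 3168 genes (22.6%), where chance gives 0.794%.

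Interferon gamma response genes rose in 21 of 24 cases, with 0 falling and 3 not passed, and also in 21 when adjusted over the list alone. Their median was 0.77 (camera adjusted p = 1.2e-11, and adjusted p = 0.270 with an estimated correlation). Cxcl9, a chemokine for activated T cells, went from 253 ± 75.9 to 753 ± 54.0 CPM (1.59, SE 0.16, adjusted p = 5.7e-05), Cxcl10 from 360 ± 44.7 to 673 ± 167 (0.92, SE 0.16), and the tryptophan-degrading enzyme gene Ido1 from 0.578 ± 0.287 to 4.40 ± 1.01 (2.94, SE 0.30). Cd274 rose by 0.85 (SE 0.12, adjusted p = 2.8e-04), Irf1 by 0.25 (SE 0.09, adjusted p = 0.034) and B2m by 0.59 (SE 0.14, adjusted p = 0.0064). Of 16 cytotoxic effector genes, 14 rose, 0 fell and 2 did not pass (15 rose when adjusted over the list alone). The cytotoxic median was 1.31 (camera adjusted p = 1.1e-09, and adjusted p = 0.270 with an estimated correlation). Gzmb, the main cytotoxic granzyme gene, rose from 21.6 ± 3.82 to 48.7 ± 3.33 CPM (1.19, SE 0.12, adjusted p = 5.1e-05), Ifng from 1.52 ± 0.287 to 5.18 ± 1.03 (1.79, SE 0.20, adjusted p = 8.0e-05) and the receptor gene Klrd1 from 3.17 ± 0.692 to 16.4 ± 4.07 (2.40, SE 0.19, adjusted p = 1.2e-05). All 11 natural killer markers rose, also when adjusted over the list alone. Their median was 1.83 (camera adjusted p = 5.7e-07, and adjusted p = 0.270 with an estimated correlation). Klre1 (2.11, SE 0.25) and Klrc1 (2.01, SE 0.24) were examples. Of 18 T cell markers, 11 rose, 0 fell and 7 did not pass (14 rose when adjusted over the list alone). The T cell median was 0.87 (camera adjusted p = 1.8e-05, and adjusted p = 0.516 with an estimated correlation). Cd8a, the co-receptor gene of cytotoxic T cells, went from 13.4 ± 4.38 to 31.9 ± 2.76 CPM (1.27, SE 0.17, adjusted p = 2.7e-04), and Cd27 rose by 1.503 (SE 0.21). In the cultured cells, 2 of the 16 cytotoxic genes, 1 of the 11 natural killer markers and 2 of the 18 T cell markers were expressed enough to be tested. Ptprc, the pan-leukocyte gene CD45, went from 49.4 ± 9.59 to 102 ± 20.8 CPM and is listed at 0 in the cultured cells, where low counts appear to have been set to 0 before deposit.

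MHC class II genes had 5 of 11 members up, 1 down and 5 not passed (8 up and 1 down when adjusted over the list alone), a median of 0.50 and a camera adjusted p of 0.026 (adjusted p = 0.583 with an estimated correlation). The list did not pass without control replicate 2 (0.0638) or control replicate 5 (0.0543), and its members with the smallest p, Ctss (0.64, SE 0.11) and H2-Aa (0.92, SE 0.20), are genes of antigen processing and peptide display. Of 19 NF-kappa-B target and cytokine genes, 9 rose, 1 fell and 9 did not pass, the same when adjusted over the list alone. That list had a median of 0.33 (camera adjusted p = 0.012, and adjusted p = 0.516 with an estimated correlation). The risers included the neutrophil chemokine gene Cxcl1 (1.95, SE 0.19), the adhesion gene Vcam1 (0.79, SE 0.09) and Tnf (0.97, SE 0.15). Endoplasmic reticulum chaperones gave 10 risers, 2 fallers and 13 not passed of 25, also when adjusted over the list alone. They had a median of 0.14 (camera adjusted p = 0.026, and adjusted p = 0.516 with an estimated correlation; 0.0801 without knockdown replicate 4). The chaperone median was 0.23 without control replicate 3 and 0.24 or 0.21 without knockdown replicate 1 or 3. Hspa5 (0.58, SE 0.10, adjusted p = 0.0011), Pdia3 (0.73, SE 0.13) and Hsp90b1 (0.58, SE 0.12) rose.

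Matrix and TGF-beta genes were lower in the knockdown tumours, with 14 of 25 down, 0 up and 11 not passed, likewise 14 when adjusted over the list alone. The median was -0.50 (camera adjusted p = 6.3e-06, and adjusted p = 0.506 with an estimated correlation), and with the correction for GC content and length it was -0.32 (adjusted p = 7.6e-05). The fibronectin gene Fn1 went from 4349.7 ± 814 to 1508 ± 260.1 CPM (-1.52, SE 0.16, adjusted p = 5.7e-05), and the collagen genes Col1a1 (-0.88, SE 0.11) and Col5a1 (-0.90, SE 0.10) fell. Vesicle traffic genes had 15 fallers, 1 riser and 6 not passed of 22, also when adjusted over the list alone. The list median was -0.37 (camera adjusted p = 7.3e-05, and adjusted p = 0.270 with an estimated correlation). Examples were Kdelr3 (-1.07, SE 0.10), Sec23a (-0.51, SE 0.08) and Creb3l2, a membrane-bound transcription factor gene (-0.56, SE 0.10). Of 23 hypoxia and glycolysis genes, 12 fell, 0 rose and 11 did not pass, likewise 12 when adjusted over the list alone. Here the median was -0.44 (camera adjusted p = 4.1e-04, and adjusted p = 0.583 with an estimated correlation). The fallers included Ldha (-0.75, SE 0.18), Pgam1 (-0.60, SE 0.15) and the carbonic anhydrase gene Car9 (-1.18, SE 0.30). Endothelial markers gave 5 fallers, 0 risers and 7 not passed of 12, the same when adjusted over the list alone. Their median log2 fold change was -0.24 (camera adjusted p = 0.017, and adjusted p = 0.516 with an estimated correlation; 0.0893 with the correction for GC content and length). The cadherin gene Cdh5 (-0.72, SE 0.16) and Vwf (-0.81, SE 0.20) were among the fallers.

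**Figure D3:**
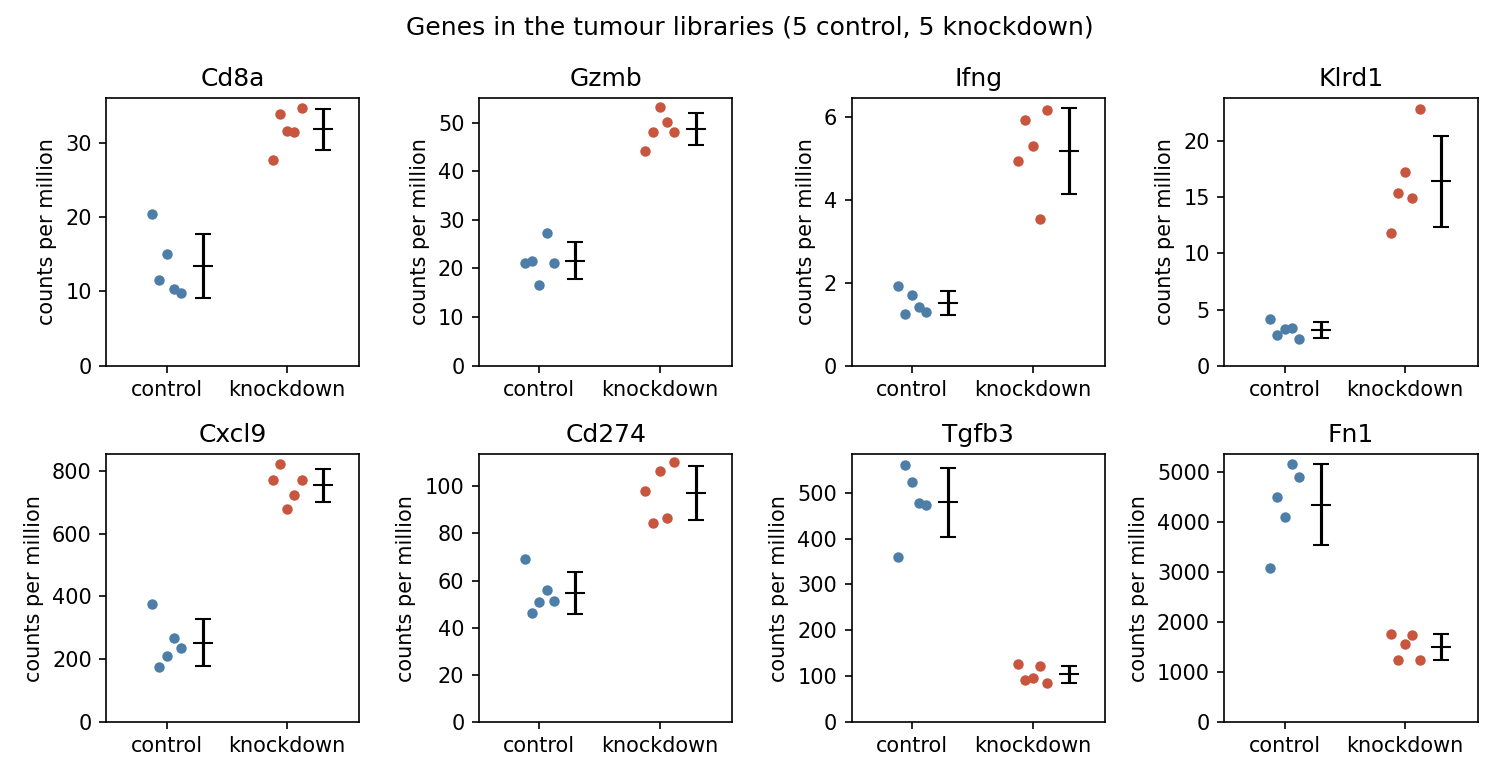
CPM (vertical axes, starting at 0) of 8 genes in each of the 5 control and 5 knockdown tumour libraries (points), with the mean and SD of each group beside them (bars). Cd8a averaged 13.4 in control and 31.9 in knockdown tumours, Gzmb 21.6 and 48.7, Tgfb3 479 and 104.

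By the size of the change, the highest rises among genes with a mean of at least 5 CPM and no overlap between the groups were the granzyme genes Gzmg (3.22, SE 0.37), Gzmf (3.19, SE 0.31), Gzmd (2.84, SE 0.37) and Gzme (2.73, SE 0.35), near-identical neighbours that share reads, so that their separate values are uncertain, with Gbp2b (2.79, SE 0.42) and Klrd1. The deepest falls under these limits were Mfap4, a microfibril protein gene (-2.81, SE 0.28), Igf2, a growth factor gene (-2.70, SE 0.21), the cartilage matrix gene Cilp (-2.70, SE 0.31), Tgfb3, which went from 479 ± 75.7 to 104 ± 19.03 CPM (-2.20, SE 0.14, adjusted p = 5.9e-06), Gpr153 (-1.86, SE 0.15) and the elastin gene Eln (-1.81, SE 0.23).

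The 10 tumour libraries also differed by group in measures of tissue make-up and RNA. Mitochondrially encoded mRNAs took 1.92% ± 0.4998 of the counts in control and 4.38% ± 1.92 in knockdown tumours (n = 5 each), with 7.07% in knockdown replicate 3 and 5.77% in replicate 5. That list had 12 of 13 members up, 0 down and 1 not passed, likewise 12 when adjusted over the list alone. The mitochondrial median was 1.20 (camera adjusted p = 2.2e-05, and adjusted p = 0.516 with an estimated correlation), and 0.65 without these 2 knockdown libraries. Xist, the RNA of the silenced X chromosome, went from 62.3 ± 9.02 to 133 ± 32.8 CPM in tumours and averaged 1.07 ± 0.218 in control cells. Skeletal muscle markers had 9 of 14 members up, 0 down and 5 not passed, also when adjusted over the list alone. The muscle median was 1.03 (camera adjusted p = 0.0059, and adjusted p = 0.583 with an estimated correlation). The creatine kinase gene Ckm stood at 46.2 CPM in knockdown replicate 2 and at most 15.3 in the other knockdown libraries, and without that library the muscle median was 0.58. Keratinocyte markers gave 2 fallers, 0 risers and 6 not passed of 8, likewise 2 when adjusted over the list alone. The keratinocyte median was -1.19 (camera adjusted p = 0.026, and adjusted p = 0.583 with an estimated correlation). The fallers were Krtdap (-3.94, SE 0.97) and Trp63 (-1.63, SE 0.53), which stood at 1.69 and 2.10 CPM in control tumours. Without knockdown replicate 5 their log2 fold changes were -6.80 and -2.54 and the list median was -2.64. The keratinocyte list did not pass without knockdown replicate 1 (0.0580), without knockdown replicate 4 (0.0603) or with a stricter filter on low counts (0.0824).

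Another 15 lists did not pass camera in the tumours. Sterol synthesis genes (median 0.16, adjusted p = 0.156) had 8 risers and 2 fallers of 25. That list passed without control replicate 1 (0.0245), without knockdown replicate 3 (0.0391) and without the 2 libraries of highest mitochondrial share (0.0199), upward each time. Medians and adjusted p were 0.14 and 0.0974 for MHC class I (0.0199 without control replicate 1 and 0.0490 without control replicate 4), 0.16 and 0.128 for immediate early genes, and -1.08 and 0.131 for adipocyte markers. The values were 0.11 and 0.131 for T cell exhaustion and regulatory T cell markers (0.0199 without control replicate 1, 0.0467 without knockdown replicate 3), -0.19 and 0.292 for fibroblast markers, -0.08 and 0.297 for lysosomal genes, 0.06 and 0.317 for proliferation, and -0.01 and 0.371 for the type I interferon response. They were 0.03 and 0.416 for macrophage markers, -0.07 and 0.438 for the integrated stress response, 0.02 and 0.650 for dendritic cell markers. The remaining lists gave -0.11 and 0.745 for fatty acid synthesis, 0.26 and 0.825 for monocyte markers, and -0.23 and 0.979 for neutrophil markers, the last with an upward camera direction. The macrophage enzyme gene Nos2 rose by 1.299 (SE 0.16), and the fibroblast receptor gene Pdgfrb fell by 1.19 on the log2 scale (SE 0.15). Of 13 fibroblast markers 4 fell and 2 rose, and that list passed fry downward (adjusted p = 0.0255). B cell and erythroid lists had fewer than 5 measured members. With the preset correlation, camera passed 14 lists for the real grouping and a median of 10 for other splits of the 10 tumour libraries. An exact permutation test of each list's mean over 252 relabelings, added after the camera results were seen, was passed by 10 of the 29 lists: interferon gamma, cytotoxic, natural killer, NF-kappa-B, chaperone, vesicle traffic and muscle lists at an adjusted p of 0.0329, the smallest these relabelings gave, and T cell, matrix and endothelial lists at an adjusted p of 0.0460.

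The third comparison asked whether the knockdown effect differed between tumours and cultured cells, by the interaction term over all 16 libraries. By camera with the preset correlation, sterol and fatty acid synthesis genes, which were lower in the knockdown cells, had a more positive effect in tumours. Matrix genes and type I interferon genes had a more negative one. These list calls were lost with an estimated correlation. Of 12581 genes tested, the effect differed in 2850, with 1598 more positive and 1252 more negative in tumours. Mbtps1 itself differed by 0.65 (SE 0.14, adjusted p = 0.0033), the fall being smaller in tumours. Tumour libraries also hold RNA of host cells, so these differences cannot be assigned to the cancer cells. Of 20 lists, 7 passed camera: sterol synthesis (more positive in tumours, adjusted p = 3.9e-08), mitochondrial mRNAs (more positive, 2.1e-04), type I interferon (more negative, 0.0059), fatty acid synthesis (more positive, 0.0065), matrix and TGF-beta (more negative, 0.0065), integrated stress (more negative, 0.017) and endoplasmic reticulum chaperones (more positive, 0.022). With the correlation estimated by camera, 0 of the 20 passed, at adjusted p from 0.670 upward, and 0 had an unadjusted p under 0.05. The interferon gamma list did not differ past the threshold (adjusted p = 0.787). For Insig1 the difference was 1.31 (adjusted p = 1.2e-04) and for Cyp51 1.12 (adjusted p = 1.0e-04).

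Among single genes with a mean of at least 5 CPM over the 16 libraries and no overlap between the groups in cells or in tumours, the most positive differences were in Chrna1, a muscle acetylcholine receptor gene (2.98, SE 0.34), Igsf6 (2.29, SE 0.60), the receptor gene Klra2 (1.99, SE 0.41), Scara5 (1.94, SE 0.38) and Galnt7 (1.82, SE 0.16). The most negative under these limits were in Ubd (-6.59, SE 1.07), Cd74, the MHC class II chaperone gene (-2.81, SE 0.90), Slamf8 (-2.77, SE 0.52), Lrrc17 (-2.72, SE 0.94) and Htra3 (-2.65, SE 0.66). With limma voom, Igsf6 (0.0513), Cd74 (0.0693) and Lrrc17 (0.332) did not pass, and Ubd differed by -4.18. Leaving out 1 library at a time, Lrrc17 lost its call for 11 of the 16 libraries, with adjusted p up to 0.193. Without control cell replicate 1, 2 or 3 or knockdown cell replicate 1 or 3, the adjusted p of Cd74 was 0.0488, 0.0671, 0.101, 0.0504 or 0.116. Igsf6 did not pass without control cell replicate 1 (0.0884) or knockdown cell replicate 3 (0.0511), and Htra3 did not without knockdown cell replicate 1 (0.0688) and differed by -4.68 without control cell replicate 1. Several of these rest on few counts in the cultured cells. Ubd, a ubiquitin-like protein gene, had 0 counts over the 3 control and 52 over the 3 knockdown cell libraries, at least 16.6-fold higher against a floor of 3 counts over the group. The ratio of knockdown to control cells was 10.8 for Cd74 (5 and 56 counts, 95% counting interval 4.34 to 34.4), 8.48 for Slamf8 (6 and 53 counts, 3.65 to 24.1), 2.18 for Lrrc17 (11 and 25 counts, 1.04 to 4.91), 2.66 for Htra3 (13 and 36 counts, 1.38 to 5.46) and 0.346 for Igsf6 (25 and 9 counts, 0.142 to 0.765). Across 11762 genes tested in both comparisons the log2 fold changes had a Pearson correlation of 0.103 and a Spearman correlation of 0.0476, over genes, which are not independent replicates. The fold changes rose with transcript GC content in cells (Spearman 0.327) and fell with it in tumours (-0.405). With transcript length the Spearman correlation was -0.393 in cells and -0.0918 in tumours. Neither this agreement nor the interaction was computed with the correction for GC content and length. What these trends contribute to either was therefore not tested. Genes higher in both numbered 120 (86.3 for independent lists) and genes lower in both 208 (132 for independent lists), with 55 higher in cells and lower in tumours (86.3 for independent lists) and 103 lower in cells and higher in tumours (131 for independent lists). The number of differing genes was 1855 without control cell replicate 3 and 1667 without knockdown cell replicate 3, and the Pearson correlation was 0.0497 without control cell replicate 2, 0.0605 and 0.0532 without knockdown cell replicates 1 and 2, and 0.167 without knockdown cell replicate 3.

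The fourth comparison asked which guides of a pooled CRISPR library in MC38 cells differed in abundance between C57BL/6 mice and Rag1-knockout mice, which lack mature T and B cells. There was 1 library per mouse genotype, so the differences have no replicate check and no p-value is given. The C57BL/6 library held 27142741 reads and the Rag1-knockout library 19114273, over 18146 guides for 4532 genes and 24 control guides. Of the 4 Mbtps1 guides, 1 had 66 reads in C57BL/6 and 551 in Rag1-knockout mice, a log2 ratio of -3.12 with a pseudocount of 1 CPM. Another had 96 and 24 reads, a log2 ratio of 1.01, so the guides went in opposite directions. The other two were below 20 reads, with 0 and 17 reads for one and 0 and 0 for the other, where a count of 0 allows up to 0.111 CPM in C57BL/6 and 0.157 in Rag1-knockout mice. The 95% counting interval of the log2 ratio without the pseudocount was -3.96 to -3.20 for the first guide and 0.84 to 2.204 for the second, and covers counting error only. The median over the 2 kept guides was -1.06, at the 5.00th percentile of 10000 random guide sets of the same size and abundance, whose central 95% ran from -1.27 to 1.36. With no minimum of reads it was -0.46 over the 4 guides. That value lies between the ratios of the 2 guides under 20 reads, and the pseudocount largely sets these. The guide with 0 reads in both libraries entered at 0. The guide with 0 and 17 reads entered at -0.92, while its counting interval without the pseudocount lay below -2.55. By median CPM of the guides, Mbtps1 ranked 6 from the bottom of 4532 genes in C57BL/6 (1.22, against a median of 45.9 over genes) and 4 from the bottom in Rag1-knockout mice (1.07, against 42.7). By reads summed over all its guides it ranked 2 from the bottom in C57BL/6 (162 reads) and 38 from the bottom in Rag1-knockout mice (592 reads). The log2 ratio of the reads summed over the 2 kept guides had a counting interval of -2.59 to -2.08.

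**Figure D4:**
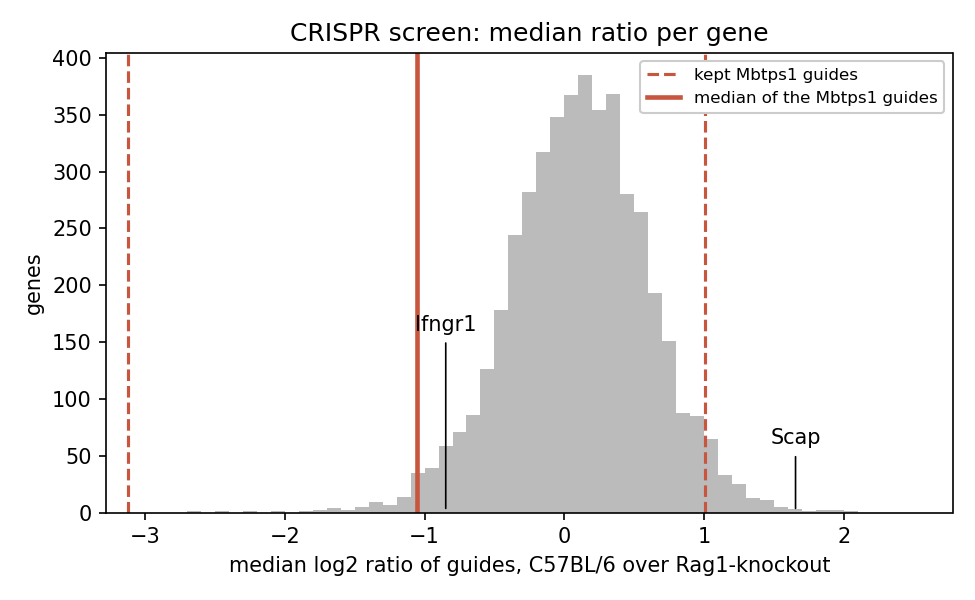
Number of genes (vertical axis) by the median log2 ratio of their guides in C57BL/6 over Rag1-knockout mice (horizontal axis), for genes with at least 3 kept guides; dashed lines are the 2 kept Mbtps1 guides and the solid line their median of -1.06. Scap (1.65) and Ifngr1 (-0.85) are marked.

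Over all 18108 guides with at least 20 reads the median log2 ratio was 0.12, and 26.0% of guides differed by more than 2-fold; scaling by control guides placed the median at 0.38 and scaling by the median ratio at 0.00. Gene medians below are on the unshifted scale. Among the lowest medians were those of Nup93 (-2.64), a nuclear pore gene, Ept1 (-2.44), Clec9a (-2.20) and Pate4 (-2.09), and among the highest those of Npc1l1 (2.06), an intestinal sterol transporter gene, Copa (1.97), a coat protein gene, the olfactory receptor gene Olfr869 (1.89) and Hspg2 (1.89). For Nup93 the 3 kept guides ran from -3.61 to -0.07 over 351 reads in C57BL/6 and 820 in Rag1-knockout mice. Its median was -1.09 with a pseudocount of 5 CPM and -1.42 with no minimum of reads. For Copa the 3 kept guides ran from -2.79 to 2.11 over 336 reads in C57BL/6 and 232 in Rag1-knockout mice, and the log2 ratio of the summed reads had a counting interval of -0.22 to 0.28. The 534 olfactory receptor genes, which MC38 cells are not known to need, had an SD of gene medians of 0.532, with a central 95% from -1.02 to 1.05. In the fixed list of interferon signalling and MHC class I genes, 5 of 20 were in the library. Ifngr1, the interferon gamma receptor gene, was lower in C57BL/6 in 4 of 4 guides (-0.85, random sets -0.81 to 1.11), and Ifnar2 (1.49, random sets -0.80 to 1.05) and Erap1 (1.09, random sets -0.85 to 1.07) lay above theirs. For Erap1 1 of 4 guides was at -1.95, and the log2 ratio of its summed reads went the other way, with a counting interval of -0.22 to -0.05. Of 17 genes of site-1 protease, its partners and substrates, 7 were in the library, and Scap, the SREBP escort gene (1.65, random sets -0.89 to 1.27), was higher in C57BL/6 in 4 of 4 guides. Of 27 immune evasion genes, 2 were in the library, Cd274 (-0.51) and Cd47 (0.49), both inside their random ranges; the list median of -0.08 was 0.17 with control-guide scaling and 0.26 as a mean over guides. Of 25 genes needed by most dividing cells, 0 were in the library.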

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

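All tests of explanations and all counts over other splits of the libraries given here were chosen after the results were seen, whereas the comparison of tumours with cells and the search for libraries apart from their group were planned.

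In the knockdown cells, mRNAs whose 3' untranslated region holds the hexamer CTCGGA were lower, by a log2 difference of -0.14 after adjustment for the region's length and GC content (SE 0.0109), the lowest of 4096 hexamers, which argues against length and GC content as the whole cause. The mRNAs with 2 or more sites lay below those with 1 site by a further -0.14 (-0.144, SE 0.0400), and in tumours the adjusted difference was -0.0406 (SE 0.0138), at rank 131. Pairing of the knockdown reagent with these mRNAs through its seed is a candidate explanation, since the Mbtps1 mRNA holds the hexamer 3 times in its coding part. However, 69.4% of shuffled Mbtps1 transcripts hold the bare hexamer too, and the reagent's sequence is not given in the sources used here. In cells, with 1 more base before the hexamer the adjusted difference ran from -0.178 (C) to -0.0601 (G). With 1 more base after it, the difference ran from -0.184 (A) to -0.0874 (C), with -0.102 for G. The 3 Mbtps1 sites each have C before them and are followed by A, G and G. The shuffles did not cover these longer words. Only 3 of 25 sterol synthesis genes hold the hexamer, and those without it still had a median log2 fold change of -0.54 in cells. Sites in the sterol mRNAs themselves therefore do not account for that fall, but an indirect effect of other lowered mRNAs was not tested. Loss of Mbtps1 itself is the explanation the design names for the sterol fall, and it remains open together with other targets of the reagent, with or without the hexamer.

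Cytotoxic, natural killer and interferon gamma response genes were higher in the knockdown tumours. A larger share of all host cells would raise every host marker, and endothelial markers instead had a median of -0.24 (exact permutation adjusted p = 0.0460), although their camera call was lost with the correction for GC content and length (0.0893) and both Xist and Ptprc rose. Without the 2 libraries of highest mitochondrial share the cytotoxic median was 1.45, and with the correction for GC content and length it was 1.05. The 3 lists passed camera upward in both with the preset correlation, so these calls did not rest on the 2 libraries or on GC content and length alone. With an estimated correlation the lists passed neither over all tumour libraries (adjusted p = 0.270 each) nor without the 2 (adjusted p = 0.351, 0.351 and 0.474). Every knockdown tumour had a mitochondrial share of at least 2.88%, and every control tumour at most 2.78%. Leaving out the 2 libraries therefore does not remove that difference and cannot decide whether it contributes. A change in particular leukocytes, in number or in activity, may underlie the rise and cannot be separated further in mixed tissue. The Mbtps1 level of the cancer cells is the biological difference that the design names, and targets of the reagent outside Mbtps1 also stay open.

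Guides against Mbtps1 had few reads in both screen libraries. Their median in Rag1-knockout mice was 1.07 CPM, against 42.7 over genes, so adaptive immunity is not needed for low reads there. By summed reads Mbtps1 ranked 2 from the bottom in C57BL/6 and 38 from the bottom in Rag1-knockout mice. Few copies before implantation, a loss of these cells in culture and a loss in mice of both kinds cannot be told apart, because no library from before implantation was analysed here. The median log2 ratio of the kept guides was -1.06, inside the range of random sets, and those 2 guides went in opposite directions, so whether adaptive immunity removed such cells cannot be told apart from chance with 1 library per genotype.

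Of 108 groups of 5 tumour libraries examined, 9 had a library apart from the others, where chance flags about 1 in 20 groups, or 5.4 here. The gap to the nearest library, as a share of the group's range, was 0.716 for the mitochondrial share of control replicate 2 (2.78%, others 1.503% to 1.87%) and 0.788 for the total count of knockdown replicate 3 (32655739). In control tumours it was 0.725 for Gbp2b in replicate 1 (5.36 CPM, others 0.780 to 2.04), 0.778 for H2-Aa in replicate 1 (1116 CPM, others 476 to 618), 0.743 for Col5a1 in replicate 3 (821 CPM, others 691 to 725) and 0.852 for B2m in replicate 2 (3501 CPM, others 2691 to 2811). In knockdown tumours it was 0.869 for Ckm in replicate 2 (46.2 CPM, others 10.6 to 15.3), 0.908 for Krtdap in replicate 5 (0.491 CPM, others 0 to 0.0449) and 0.949 for Trp63 in replicate 5 (1.96 CPM, others 0.315 to 0.398).

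The knockdown effect differed between tumours and cells, by the interaction test of edgeR, in 31 of the 55 named genes measured in both. Many of these genes were named for a large change or a small p in cells or in tumours. The interaction was tested on the same libraries, so that choice favours a difference. The share among named genes therefore does not apply to genes in general. Over all 12581 genes tested, the effect differed in 2850. Values are the log2 effect in tumours, whose libraries also hold host RNA, minus that in cells. In lipid genes it was 1.12 for Cyp51, 0.89 for Idi1, 1.31 for Insig1, 0.83 for Elovl6 and 0.87 for Scd1. Chaperone genes gave 0.46 for Hspa5, 0.80 for Pdia3 and 0.71 for Hsp90b1. Interferon, presentation and inflammatory genes gave -2.09 for Zbp1, -0.52 for Bst2, -1.31 for Ifit3, -0.98 for Socs1, -0.94 for Psmb10, -1.07 for Tgtp2, 0.71 for B2m, 1.09 for Cxcl1 and 0.82 for Vcam1. Matrix and growth factor genes gave -1.40 for Fn1, -2.39 for Col1a1, -1.77 for Tgfb3, -1.60 for Gpr153 and -0.93 for Pdgfrb, and stress genes -0.93 for Ddit3 and -1.67 for Hspa1b. Mbtps1 gave 0.65, Gpr153 -1.60, Prrx2 -2.68, Acpp 1.72, Wasf1 1.43, Galnt7 1.82, Tmem185a 1.27 and Lmtk2 1.40.

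The 9 other genes taken for the size of the difference were Chrna1 (2.98), Igsf6 (2.29), Klra2 (1.99), Scara5 (1.94), Ubd (-6.59), Cd74 (-2.81), Slamf8 (-2.77), Lrrc17 (-2.72) and Htra3 (-2.65). Ubd had 0 counts in control cells, so the size of its difference depends on the fit, and it was -4.18 with limma voom. The lists that differed had camera adjusted p of 3.9e-08 for sterol synthesis, 2.1e-04 for mitochondrial mRNAs, 0.0059 for type I interferon, 0.0065 each for fatty acid synthesis and matrix genes, 0.017 for integrated stress and 0.022 for chaperones. With an estimated correlation 0 of the 20 lists passed, at adjusted p from 0.670 upward, and 0 had an unadjusted p under 0.05.

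Regrouping the libraries bears on the counts of calls. For the 3 against 3 cell libraries the 10 splits are too few for a share under 0.05: 1 of the 10, the real one, reached 1111 genes and the highest other called 1, and for gene lists the real split passed 9, 2 of the 10 passed at least as many, and the highest other passed 10. For the tumour gene count 1 of 100 splits, the real one, reached 5377 genes and the highest other 2088, which argues against a random division of these libraries. The labels do not state that the libraries were separate animals. A chance difference between the tumours behind the 2 groups is therefore not excluded. For the tumour gene lists chance cannot be excluded, since 28 of 100 splits passed at least the 14 lists of the real one and the highest other passed 19. For the interaction 1 of 100 splits, the real one, reached 2850 genes and the highest other 1792. These splits mix control and knockdown libraries within cells and within tumours. They therefore remove the knockdown effects themselves and cannot decide whether the effects differ between tumours and cells.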

How the results depend on the processing

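The correction for GC content and length, the tumours without 2 libraries, the cells without genes holding the hexamer and the exact permutation test were chosen after seeing the data. The fall of Mbtps1 passed under every alternative run in cells and tumours, and no called list or named gene past the threshold changed direction under any. Over all genes, 1 gene called in cells was called in the opposite direction with the correction for GC content and length. With that correction 1490 genes were called in cells, of which 836 were shared with the 1111 called without it. In tumours it gave 4080 genes, of which 3221 were shared with the 5377. In the screen, the immune evasion median of -0.08, which has no test, was 0.17 with control-guide scaling and 0.26 as a mean over guides. In cells, against 1111 changed genes, glmTreat called 48 (its test is against a fold of 1.5), limma voom with sample quality weights 2667, and leaving out 1 library 290 (control replicate 1) to 1531 (knockdown replicate 2), with 466 without control replicate 2 and 330 without knockdown replicate 1. In tumours, against 5377, glmTreat called 245 for the same reason. The replicate block gave 508 genes in cells, 502 of them shared with the calls without it and 0 opposite in direction; in tumours it gave 4746 genes, and 2177 against 2850 for the interaction. Same-numbered libraries correlated at -0.189 to 0.0515 in cells and -0.203 to 0.158 in tumours, and 2 of 6 and 2 of 10 correlated best with their own number, so the numbers do not pair the libraries. Of 9 lists in cells and 14 in tumours, camera with an estimated correlation passed 0 and 0 (2 and 4 at an unadjusted p under 0.05), and over all lists tested fry passed 3 of 17 in cells and 13 of 29 in tumours. The fit over all 16 libraries, with only genes that have counts in both parts, passed 7 lists in tumours: 6 of the 14 had fewer than 5 members left and were not tested, and the endothelial list did not pass (0.127). For the interaction, leaving out 1 library gave 1667 (knockdown cells 3) to 3359 genes (knockdown tumour 1), with 1855 without control cells 3. The correlation of effects, 0.103, ran from 0.0497 (without control cells 2) to 0.167 (without knockdown cells 3). The screen median of Mbtps1 was -0.46 with no minimum of reads, over 4 guides in place of 2. Of these guides, 1 had 0 reads in both libraries and entered at 0 through the pseudocount alone. Where no reason is given, the cause was not tested. Of alternatives for named genes, 1051 of 1214 in cells and 2087 of 2199 in tumours kept the side of the threshold, and 157 and 103 lost it. For lists 240 of 271 and 516 of 569 did. For the screen 90 of 133 stayed within a margin, and 43 moved by more or changed sign. The margin came from the counting intervals for genes and was a fixed value for lists, so it is not a spread between libraries. With 3 libraries per group, 53.2% of simulated changes by a fold of 1.5 were found, so part of the changes of that size was missed, and genes under about 13 counts, missing from the cell part, could not be assessed.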

Other observations

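The genes and families described here, and the test of the imprinted genes, were chosen after the values were seen.

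Chemokine ligand genes were higher in the knockdown tumours. Of 27 measured, 15 rose, 3 fell and 9 did not pass, with a median log2 fold change of 0.72 (exact permutation p = 0.00794 over 252 relabelings, the smallest they can give). Ccl5, which attracts T cells, rose from 129 ± 28.6 to 279.7 ± 29.1 CPM (n = 5 each, 1.14, edgeR adjusted p = 1.2e-04), and Ccl8 rose by 1.40. The fallers included Ccl22 (-1.11) and Ccl17 (-1.70), ligands of regulatory T cells, and Ccr7, a receptor of migrating dendritic cells, was lower too (-0.77, adjusted p = 0.027). The dendritic cell genes Xcr1 and Clec9a rose by 1.70 and 0.95, though Clec9a also stood at 21.8 CPM in control cells in culture, and the fixed list of dendritic cell markers had 3 risers, 3 fallers and 7 not passed (median 0.02, camera adjusted p = 0.650). Foxp3, the regulatory T cell factor, did not pass (-0.31, adjusted p = 0.41), nor did the checkpoint gene Pdcd1 (0.61, adjusted p = 0.13), while Ctla4 rose by 1.02 (adjusted p = 0.0058). In cultured cells 5 of 8 chemokine ligand genes rose. Genes that passed the same way in cells and tumours included Ccl5 (1.42 in cells), Il15, which sustains natural killer cells (1.03 and 0.83), and Il33, an alarmin (-2.46 and -1.18).

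Matrix protease genes of the Mmp and Adamts families were lower in the knockdown tumours, with 14 fallers, 1 riser and 17 not passed of 32 (median -0.35, exact permutation p = 0.00794). In cells, 3 of 22 rose and 0 fell with edgeR. Mmp9, a gelatinase gene, rose in cells (1.10, adjusted p = 0.0014) and fell in tumours (-0.62, adjusted p = 0.0029), and the effects differed by -1.69 (adjusted p = 8.4e-05). All 3 TGF-beta ligand genes fell in tumours, Tgfb1 (-0.53), Tgfb2 (-1.78) and Tgfb3 (-2.20). The TGF-beta response genes Pmepa1 (-1.23) and Snai1 (-1.28) fell as well.

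A pair of imprinted growth genes was lower in the knockdown tumours. H19 went from 6619 to 2926 CPM (-1.17, adjusted p = 3.2e-04) and Igf2 fell by 2.704 on the log2 scale, while in cultured cells H19 went from 3.67 to 1.14 CPM (-1.69, adjusted p = 0.042). In cells 9 imprinted genes of the list were measured, with 1 faller, 0 risers with edgeR and 8 not passed (8 of 9 negative, median -0.30). Their mean differed by -0.38 there, at an exact permutation p of 0.10, the smallest that 20 relabelings can give, with camera p = 0.0192 and p = 0.282 with an estimated correlation. The hypothesis that imprinted growth genes were lower as a group was tested on the 13 other genes of a list, of which 3 fell, 0 rose with edgeR and 10 did not pass (median -0.10). Their mean was lower by 0.29 (exact permutation p = 0.0159), but camera did not pass (p = 0.121, and p = 0.259 with an estimated correlation). A modest group effect may be present beside the large fall of H19 and Igf2, and a different share of host cells with high H19 stays open.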
